A study of Mus musculus with 10 samples.

How the data were processed

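Total RNA from microdissected hindbrain and pharyngeal arch tissue was converted to biotin-labelled RNA with a 3' IVT kit and hybridised to Affymetrix arrays, per the labels' protocols. The embryos came from crosses of heterozygous carriers of the Fbln1 gene trap, and genotypes were read from yolk sac, per the labels' protocols. The study design counts 5 embryos per genotype. The labels do not say which embryos were littermates, so the p-values measure the spread between these samples. The authors deposited log2 expression values made with GCRMA, per the submitters' processing notes, with no version given in the sources used here. GCRMA corrects for background from probe sequence, normalizes across arrays and gives 1 value per probe set, and it pulls dim probe sets to a common floor. The values ran from 2.22 to 14.8, so fold changes of dim genes such as Fbln1 are compressed. Detection calls and probe intensities were not used here.

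The table held 22690 probe sets, of which 64 controls were left out of the tests. Of the remaining 22626, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. Only those with 1 symbol were given a name. Of the named probe sets, 20351 had a symbol found in the RefSeq gene table for assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. No genome build was named for the arrays, and no coordinates are given. Probe sets ending in _x_at or _s_at can match transcripts of several genes. Among the genes named in the text they read Pim3, Bpgm, Gpt2, Suds3, Spred1, Fgfr2, Gli2, Aldoa, Ccn1, Ets1 and Xist, and 2 of the 3 probe sets of Ift27.

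A probe set was kept if its log2 value was over 4 on at least 5 of the 10 arrays, whatever the genotype, which left 9801. These stood for 5912 genes, each represented by its brightest kept probe set. Null and wildtype arrays were compared with limma (lmFit and eBayes, version 3.58.1 in R 4.3.3) with genotype alone in the model, two-sided, and Benjamini-Hochberg adjustment over the probe sets kept. The threshold was an adjusted p of 0.05. Fbln1, Fgf8 and sex-linked probe sets were fitted among all 22626. Single values per array were compared with exact permutation tests over all assignments of 5 and 5 arrays, whose smallest two-sided p is 0.00794.

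Gene lists for the tissue, its signalling pathways, neighbouring tissues and stress held 648 distinct genes. Of these lists 23 with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. The fibulin family and the liver, yolk sac and gut list had fewer than 3 genes over the filter and were not tested.

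The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Fbln1 and Fgf8, the genes past the threshold and those next in order of p up to 10 in each direction, list members past the threshold over all genes or over the list alone, the 3 members with the smallest p in each list described, and the sex-linked genes. The remaining FGF members, the FGF genes under the filter and the genes next to Fbln1 were chosen after their values were seen. The alternatives covered scaling, filter, floor, variance model, array weights, a block on the replicate number, embryo sex from Xist and Y-linked signal, each array left out in turn, and thresholds. A covariate for the actin probe ratio and a fit without wildtype replicates 1 and 2 were added after the data were seen.

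The fits were tested on simulated data with 200 of 9801 probe sets changed. At an adjusted p of 0.05 they recovered 20.8% of changes of log2 0.5, 76.9% of log2 1, 95.2% of log2 1.5 and 98.1% of log2 2, and 4.3% of calls were unchanged probe sets. With no change simulated the mean number of calls was 0. Camera passed 4% of unshifted simulated lists at an unadjusted p of 0.05. The simulated probe sets were independent of each other, so these rates do not hold for correlated genes. In the 4 lists that pass below, the estimated correlation was 0.27 to 0.52.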

Results

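Gene expression was measured on Affymetrix arrays in microdissected mouse tissue that held the hindbrain and pharyngeal arches 1 to 4 at stage E10.5. The arches are the embryonic swellings that give rise to structures of the face and neck. The 10 arrays fell into 5 from wildtype embryos and 5 from Fbln1-null embryos of a gene-trap strain. Fbln1 encodes fibulin-1, a secreted glycoprotein of the extracellular matrix and basement membranes. The series asked how the loss of fibulin-1 affects signalling by FGF8, a fibroblast growth factor needed for growth of the arches. Array medians lay between 3.20 and 3.29 on the log2 scale, and 9618 to 9943 probe sets per array had a value over log2 4. Correlations between arrays across probe sets were 0.985 to 0.996, and 0 pairs of arrays were identical. Probe sets are not independent replicates, and the number of arrays limits the precision of every value below.

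Fbln1 signal was lower in all 5 null arrays than in any wildtype array. On the brighter of its probe sets the log2 signal was 4.55 ± 0.50 (SD, n = 5) in wildtype and 2.66 ± 0.13 (SD, n = 5) in null tissue, a log2 fold change of -1.88 (SE 0.22). The wildtype arrays spanned 3.83 to 5.11 and the null arrays 2.52 to 2.85 (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 arrays can give). The dimmer Fbln1 probe set had 3.53 ± 0.53 in wildtype and 2.41 ± 0.27 in null tissue (log2 fold change -1.12, SE 0.25, exact permutation p = 0.00794), but 3 of its 5 null arrays read 2.26, the bottom of the scale, so this size is a lower bound. Fgf8 itself read 2.26 in both genotypes and gave no fold. Both Fbln1 probe sets were dim and under the expression filter, and over all 22626 probe sets the Benjamini-Hochberg adjusted limma p was 0.0715 for the brighter and 0.303 for the dimmer. Raising values under log2 4 to 4 left a log2 fold change of -0.58 for the brighter one, a lower bound on its size, and without wildtype replicate 3 its adjusted p was 0.0173.

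**Figure D1:**
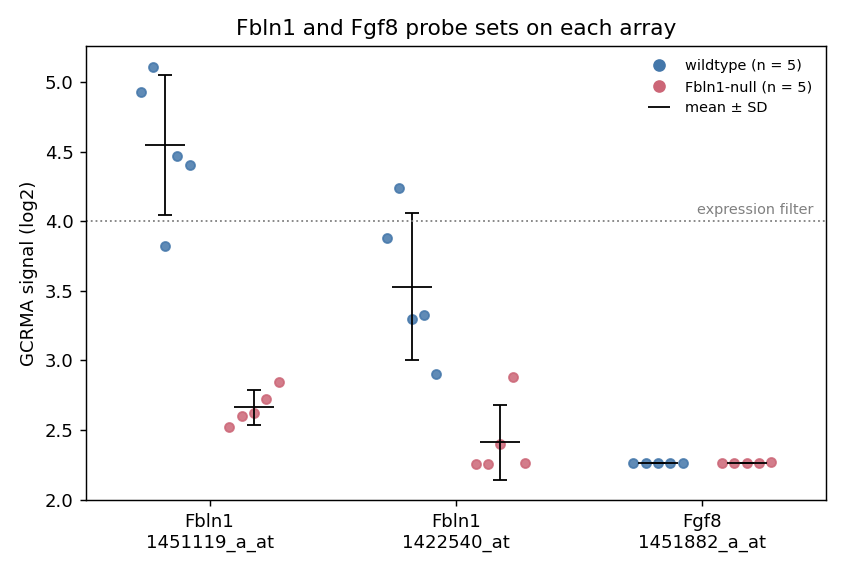
GCRMA signal (log2, vertical axis) of the Fbln1 and Fgf8 probe sets on each of the 5 wildtype and 5 Fbln1-null arrays, with the mean and SD of each group and the expression filter at log2 4 as a dotted line. For the brighter Fbln1 probe set the null arrays lie between 2.52 and 2.85 and the wildtype arrays between 3.83 and 5.11, while Fgf8 reads 2.26 in both genotypes.

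Pole4 and Htatsf1 fell in null tissue. Pole4, a histone-fold subunit of DNA polymerase epsilon, had a log2 signal of 7.43 ± 0.15 (SD, n = 5) in wildtype and 6.45 ± 0.13 in null tissue (log2 fold change -0.98, SE 0.12, 1.98-fold, limma adjusted p = 0.0196). Htatsf1, an RNA-binding factor of transcription elongation and splicing, went from 9.62 ± 0.12 to 8.64 ± 0.22 (log2 fold change -0.98, SE 0.13, 1.97-fold, limma adjusted p = 0.0292). All 5 null arrays lay below the wildtype range for both. The dimmer Pole4 probe set did not follow the brighter one, with a log2 fold change of 0.07 (SE 0.12, limma adjusted p = 0.852). These were the 2 probe sets past an adjusted p of 0.05 among 9801 tested, with 0 higher. Without wildtype replicate 1, 2 or 4, or null replicate 5, 7 or 8, the count was 0, and it was 1 without wildtype replicate 5 and 7 without wildtype replicate 3. With embryo sex in the fit, a covariate that mostly marks wildtype replicate 4, the log2 fold changes of Pole4 and Htatsf1 were -0.93 and -0.94. With the actin probe ratio they were -0.90 and -0.96. In both fits 0 probe sets were past the threshold, while a filter at log2 6 or array weights gave 34.

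Genes next in order of p did not pass the threshold, and all of them had the 5 null arrays outside the wildtype range. Among the lower ones, Dvl1, a cytoplasmic transducer of Wnt signals, had a log2 fold change of -0.94 (SE 0.14), and Mapk14, a stress-activated MAP kinase, -1.12 (SE 0.18). Pim3, a serine/threonine kinase, had -1.44 (SE 0.24) and Snrpc, a protein of the U1 spliceosomal particle, had -0.98 (SE 0.16). Ndufa9, a subunit of respiratory complex I, had -0.82, St3gal3, a sialyltransferase, -0.82, Bpgm, a mutase of red cell glycolysis, -0.67, and Ei24, a membrane protein induced by p53, -0.65. The limma adjusted p was 0.0633 for each of these 8 genes. Among the higher ones, Timmdc1, an assembly factor of respiratory complex I, had 0.82 (SE 0.14, limma adjusted p = 0.0633). Gpt2, a mitochondrial alanine aminotransferase, had 0.83, Suds3, a subunit of the Sin3 corepressor complex, 0.61, and Polr3gl, a subunit of RNA polymerase III, 1.45, each with a limma adjusted p of 0.0781. The wildtype mean of Polr3gl, 3.64, was under the expression filter, and with values under log2 4 raised to 4 its log2 fold change was 0.95. Pim3, Bpgm, Gpt2 and Suds3 were read on probe sets of types that can match transcripts of several genes. Rbpj, the DNA-binding effector of Notch signalling, had 0.72, Tfap2c, an AP-2 transcription factor, 0.76, and Rad52, a recombination protein, 0.62. Qrich1 had 0.83, Zfp280d 0.73 and Ippk, an inositol phosphate kinase, 0.54, and the limma adjusted p of these last 6 genes was 0.107 to 0.127.

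At an adjusted p of 0.1 the limma fit gave 46 probe sets, 8 higher and 38 lower. That count was 6 with quantile normalization, 17 without a filter, 4 with the sex covariate and 3 with the actin probe ratio. It was 1 to 40 with 1 array left out, 81 with a log2 6 filter and 124 with array weights. At an unadjusted p of 0.05 it gave 1215 of 9801, of which 376 were higher and 839 lower, or 69.1% lower. With quantile normalization between arrays the lower share was 53.3%. The 2 genotypes did not overlap on 271 probe sets (2.77%), against 0.794% on average by chance. Of the 20 genes named as called or next in order of p, 8 had further probe sets over the filter. Of those 9 further probe sets, 8 shared the direction of the brighter one, 1 (Pole4) did not, and 0 had an unadjusted p under 0.05 in the limma fit. Their median absolute log2 fold change was 0.18, against 0.72 for the brighter ones. The genes were picked by p on the brighter probe set, so a smaller change on the others was likely beforehand. The further probe sets of Bpgm, Pole4, Rad52, Rbpj and Tfap2c and the dimmest of Gpt2 had wildtype means of 4.51 to 4.92. These lie near the filter, where fold changes can be compressed, so the contrast does not decide. Among all genes whose brightest probe set had an unadjusted limma p under 0.05, 74.3% of second probe sets shared its direction.

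**Figure D2:**
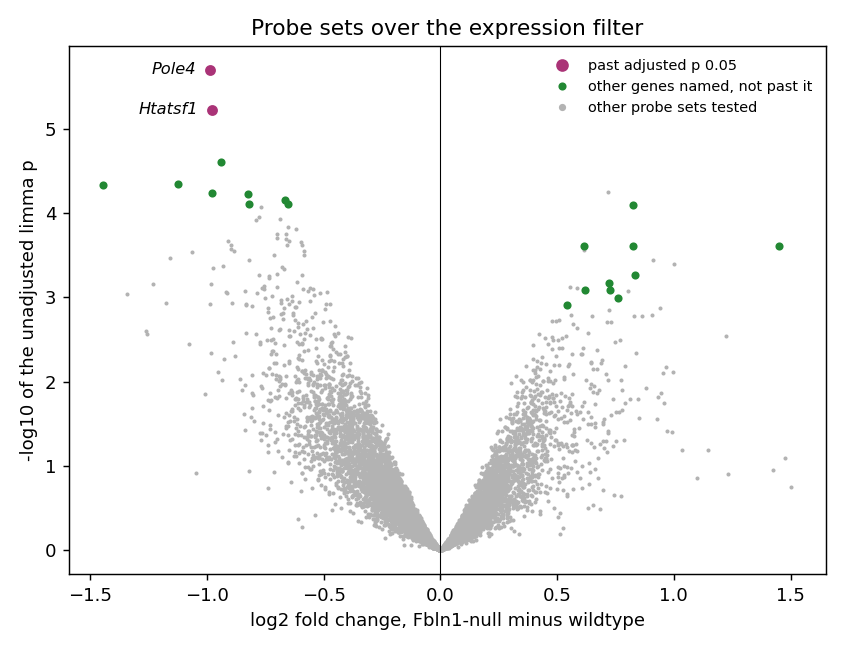
Log2 fold change between Fbln1-null and wildtype tissue (horizontal axis) against the -log10 of the unadjusted limma p (vertical axis) for the 9801 probe sets over the expression filter. Pole4 and Htatsf1, each with a log2 fold change of -0.98, are the 2 past an adjusted p of 0.05.

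**Figure D3:**
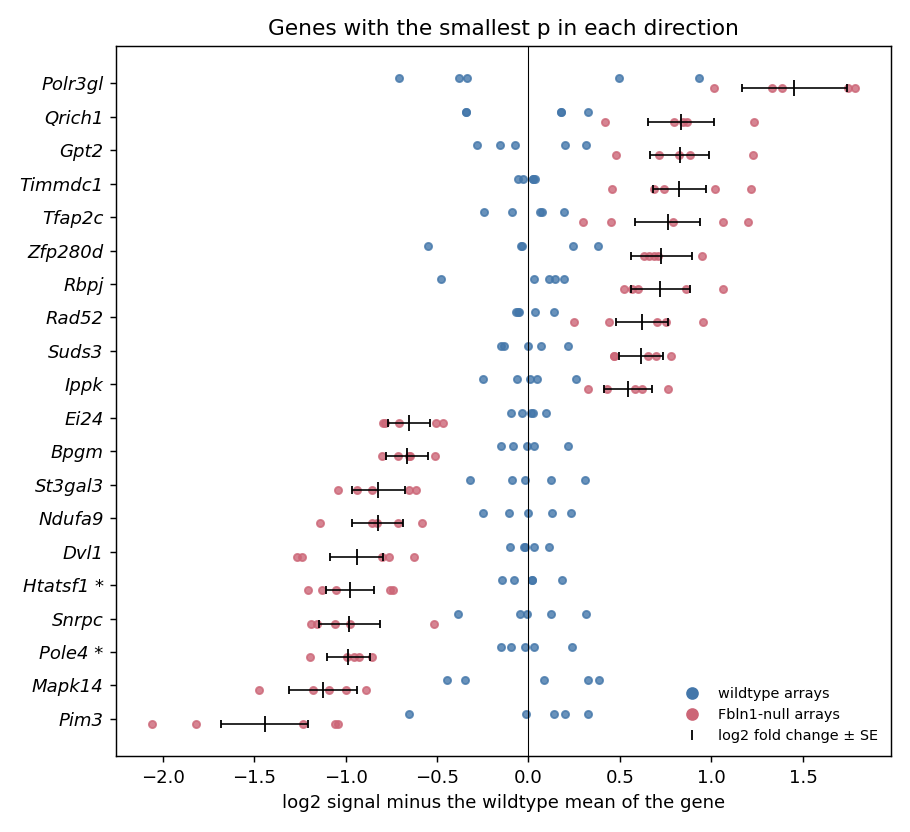
Log2 signal of each array minus the wildtype mean of the gene (horizontal axis) for 20 genes, with 5 wildtype and 5 Fbln1-null arrays per gene and the log2 fold change with its SE as a black bar. In each gene the 5 null arrays lie outside the wildtype range, and the asterisk marks Htatsf1 and Pole4, the 2 genes past an adjusted p of 0.05.

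Feedback and target genes of FGF signalling were measured to address FGF8 signalling in the tissue. Of the 7 genes over the filter, 6 had a higher mean in null tissue and 0 passed the test, over all genes or adjusted over the list alone. Spred1, a membrane inhibitor of the Ras-ERK pathway, had a log2 fold change of 0.42 (SE 0.16, limma adjusted p = 0.323), Lhx8, a LIM-homeodomain factor of the first arch, 0.41 (SE 0.16) and Dusp6, the ERK phosphatase induced by FGF signals, 0.45 (SE 0.34). The other Spred1 probe sets, of like brightness, had 0.12 (SE 0.11) and 0.15 (SE 0.22). Spry2, a feedback inhibitor of receptor tyrosine kinases, had 0.28 (SE 0.25), Myc 0.27, Egr1 0.16 and Ccnd1, the cyclin of the G1 phase, -0.19, with -0.19 and -0.48 (SE 0.18) on its dimmer probe sets. Myc and Egr1 also belong to the immediate early and heat shock list below, and Ccnd1 to the cell cycle and Wnt lists. As a list they rose against the other genes, with a median log2 fold change of 0.28 (camera with the preset correlation, p = 0.00584, adjusted p = 0.0336 over 23 lists). With an estimated correlation between genes the list did not pass (p = 0.117, adjusted p = 0.822). The list score of an array is the mean of the list's genes, each as a deviation from its mean over all arrays. For the FGF list this score was 0.13 ± 0.29 (SD, n = 5) in null and -0.13 ± 0.22 in wildtype tissue, a difference not past 0.05 (exact permutation p = 0.159). A further 10 listed genes on the array were under the filter, among them Etv4, Etv5, Spry1 and Spry4, whose wildtype means were 2.27 to 2.31. Without wildtype replicate 3, 4 or 5, or null replicate 3, 4 or 7, the adjusted camera p of the list was 0.0726 to 0.193, and the median without null replicate 7 was 0.19 (unadjusted p = 0.0606) and without null replicate 8 0.45. With the actin probe ratio in the fit the median was 0.15 (unadjusted p = 0.0997), and the adjusted p was 0.0514 to 0.114 without a filter (median 0.05), with a log2 6 filter, array weights, the sex covariate or the mean of a gene's probe sets.

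Few FGF ligands and receptors could be measured. Of 31 on the array, 5 were over the filter, and their list did not pass (median log2 fold change -0.01, camera adjusted p = 0.620), with a median sign that depended on the scaling of the arrays. Their list score, a mean over the 5 genes, was lower in null arrays by 0.21 (exact permutation p = 0.0238, not adjusted over the lists). Fgf13, an intracellular FGF homologue, had a log2 fold change of -0.89 (SE 0.25) and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0167), but 0 passed over all genes (limma adjusted p = 0.188). Fgfr2, a receptor of the family, had -0.26 (SE 0.14) and Fgf14 0.06 (SE 0.14).

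By camera with the preset correlation, Hedgehog pathway genes fell as a list, and neuronal genes and genes of hypoxia and glycolysis rose as lists. Their list scores per array did not differ between the genotypes. The exact permutation p was 0.0952 for the Hedgehog, 0.405 for the neuronal and 0.365 for the hypoxia list. All 6 Hedgehog genes tested had lower means in null tissue (median log2 fold change -0.35, camera adjusted p = 0.0336, p = 0.165 with an estimated correlation). Ptch1, the Hedgehog receptor and a target of the pathway, had -0.70 (SE 0.15), Boc, a co-receptor, -0.38 and Gli2, a transcriptional effector, -0.32. Ptch1 was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.00321), with a limma adjusted p of 0.107 over all genes. Of 17 neuronal genes 14 were higher (median 0.12, camera adjusted p = 0.0305, p = 0.281 with an estimated correlation), with the smallest p for Snap25, of the synaptic fusion complex, at 0.46, Neurod4, a proneural factor, at 0.42 and Nefl, a neurofilament subunit, at 0.48. Of 21 genes of hypoxia and glycolysis 14 were higher (median 0.13, camera adjusted p = 0.0305, p = 0.251 with an estimated correlation). Pdk1, an inhibitory kinase of pyruvate dehydrogenase, had 0.64, Vegfa, an angiogenic growth factor, 0.40 and Aldoa, a glycolytic aldolase, 0.44. Within the neuronal and hypoxia lists 0 members passed, over all genes or adjusted over the list alone.

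Of the 23 lists 0 passed (camera) with an estimated correlation, the sex covariate, a log2 6 filter or the mean of a gene's probe sets, against 4 at the settings above. Without a filter these 3 lists had an adjusted p of 0.0514 to 0.0995, with medians of 0.10 (neuronal), 0.08 (hypoxia) and -0.08 (Hedgehog). The neuronal list had a median of 0.01 (adjusted p = 0.406) without wildtype replicate 4, 0.01 (adjusted p = 0.364) with the sex covariate, 0.01 (adjusted p = 0.981) with the actin probe ratio in the fit and 0.07 (adjusted p = 0.0726) without null replicate 4. It passed with medians of 0.08 without wildtype replicate 5, and 0.21 to 0.25 without wildtype replicate 1 or 3 or null replicate 8. The hypoxia list had a median of 0.05 (adjusted p = 0.237) without null replicate 4, whose list score was 0.497 against -0.240 to 0.0874 in the other null arrays, and 0.23 without null replicate 7. With the actin probe ratio its median was 0.07 (adjusted p = 0.391), and its adjusted p was 0.0548 to 0.131 without wildtype replicate 3, 4 or 5. Wildtype replicates 1 and 2 had Hedgehog list scores of 0.556 and 0.412, against -0.0839 to 0.0110 in the other wildtype arrays, and without both the Hedgehog median was -0.09 (adjusted p = 0.541). Without wildtype replicate 1 alone it was -0.23 (adjusted p = 0.137), and the adjusted p was 0.0548 to 0.147 without wildtype replicate 2 or 4 or null replicate 4, 7 or 8.

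At the same settings, cell cycle genes, neural progenitor genes, matrix genes, neural crest genes and genes of regional identity did not pass as lists. Of 36 cell cycle genes 27 had lower means (median log2 fold change -0.16, camera adjusted p = 0.123), with E2f1, a transcription factor of S-phase entry, at -0.70, Ccne1, a cyclin of S-phase entry, at -0.64 and Mcm6, a subunit of the replicative helicase, at -0.24. The cell cycle list score was lower in null arrays (exact permutation p = 0.0238, not adjusted over the lists). Camera with an estimated correlation gave p = 0.143 for this list. Of 15 neural progenitor genes 11 had lower means (median -0.21, camera adjusted p = 0.149), with Pax6 at -0.52 (SE 0.15), Neurog1, a proneural factor, at -0.52 and Neurog2 at -0.48. Of 12 genes of hindbrain regional identity 11 had lower means (median -0.22, camera adjusted p = 0.288), with Meis2, a Hox cofactor, at -0.28, Hoxb5 at -0.52 and Hoxb3 at 0.22. Wildtype replicates 1 and 2 stood apart in both lists. Their scores were 0.319 and 0.454 for regional identity (other wildtype arrays -0.128 to -0.0358), and 0.291 and 0.264 for progenitors (others -0.0938 to 0.0623). Matrix and basement membrane genes had a median of 0.08 (camera adjusted p = 0.123), with Lama1, a laminin chain, at -0.49, Has2, the hyaluronan synthase, at 0.33 and Lamc1 at 0.29. Neural crest and arch mesenchyme genes had a median of 0.03 (camera adjusted p = 0.149), with Erbb3 at -0.39, Nr2f2 at 0.31 and Ets1 at 0.41. In these 5 lists 0 members passed, over all genes or adjusted over the list alone. By camera at other settings, the cell cycle list passed without a filter and the progenitor list with the actin probe ratio. The matrix list passed without wildtype replicates 1 and 2 together or without null replicate 7. The neural crest list passed without wildtype replicate 1 or without both replicates 1 and 2.

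Stress lists passed a test of mixed directions and not a directional one. By fry's test of change in either direction, which is not set against other genes, the immediate early and heat shock list (adjusted p = 0.0282) and the p53 and apoptosis list (adjusted p = 0.00310) passed, while by its directional test 0 lists did. At an unadjusted limma p of 0.05 stood 2 of 17 and 2 of 13 genes (11.8% and 15.4%), against 12.8% of all genes. Dnajb1, a heat shock co-chaperone, had a log2 fold change of -0.91 (SE 0.18, adjusted p = 0.00360 when adjusted over the list alone, limma adjusted p = 0.0781 over all genes), Ccn1 -0.63 and Jund -0.45. Ei24, given above, passed adjusted over the list alone (adjusted p = 0.00103), beside Aen, an apoptosis nuclease, at -0.46 and Plk2, a polo-like kinase, at 0.47. The medians of the lists, -0.17 and 0.07, did not pass camera (adjusted p = 0.547 and 0.953).

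Markers of tissues that a dissection could carry along did not pass as lists. The medians were 0.07 for erythroid cells, -0.12 for heart and outflow tract, -0.03 for endothelium, 0.07 for leukocytes, 0.01 for skeletal muscle and somite, -0.02 for forebrain, midbrain and eye, and 0.03 for otic vesicle and placodes. Pharyngeal endoderm and ectoderm had 0.003, Wnt genes 0.04, BMP and TGF-beta genes -0.04 and retinoic acid genes -0.02, and the adjusted camera p of these 11 lists was 0.511 to 0.982. Pax6, also in the forebrain list, passed adjusted over that list alone (adjusted p = 0.0299), with a limma adjusted p of 0.222 over all genes. In 7 of the 23 lists the median, the mean and the test differed in sign, and in 4 the sign of the median depended on the scaling of the arrays. None of these was past the threshold.

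**Figure D4:**
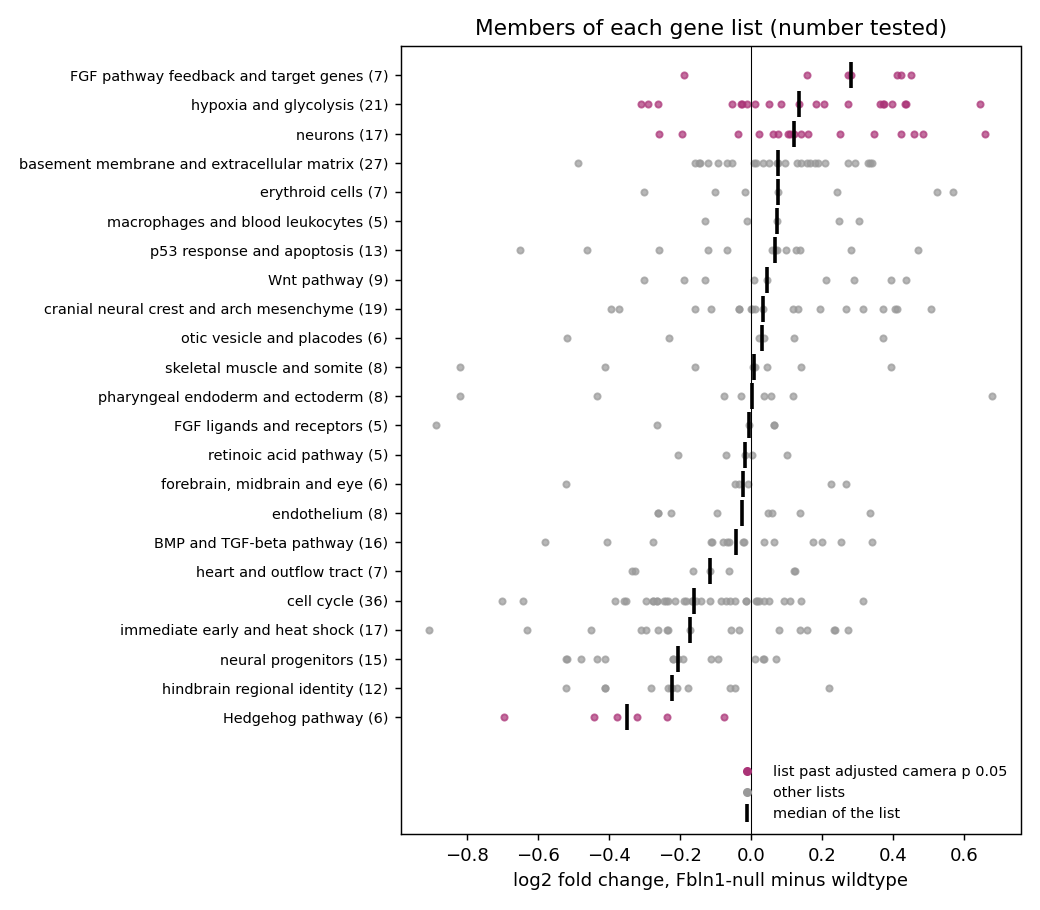
Log2 fold change between Fbln1-null and wildtype tissue (horizontal axis) of each gene in the 23 lists tested, 1 list per line with its number of genes in brackets and its median as a black bar. The FGF list (median 0.28), the hypoxia list (0.13), the neuronal list (0.12) and the Hedgehog list (-0.35) are those past an adjusted camera p of 0.05 with the preset correlation, and 0 passed with an estimated one.

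Sex-linked transcripts set 1 array apart, and 2 arrays resembled each other. Wildtype replicate 4 had an Xist signal of 9.68, a transcript of the inactive X chromosome, and signals of 2.70 for the Y-linked genes Eif2s3y and Kdm5d. The other 9 arrays had Eif2s3y signals of 8.96 to 9.85. The sex covariate was -7.17 in wildtype replicate 4 and 1.26 to 2.69 in the other arrays. A fit with it is thus close to a fit without that array. The ratio of 3' to 5' beta-actin probe sets, a sign of RNA integrity, was 2.26 ± 0.15 (log2, SD, n = 5) in wildtype and 2.48 ± 0.25 in null arrays (exact permutation p = 0.143). For GAPDH it was 1.96 ± 0.24 and 1.81 ± 0.17 (exact permutation p = 0.302). The first principal component held 24.3% of the variance and did not separate the genotypes (exact permutation p = 0.762), while the third, with 16.0%, did (exact permutation p = 0.00794). Wildtype replicates 1 and 2 deviated together from the mean of all arrays (correlation across probe sets 0.57), where any other pair had at most 0.28.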

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

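The Dixon limit for a single array far from the other 4 of its genotype was fixed before the data were examined. It was passed in 7 of 64 groups of 5 arrays, where chance gives about 3.2. Wildtype replicate 4 accounted for 3 of them, with Xist at 9.68 (others 2.34 to 2.66), Eif2s3y at 2.70 (others 8.96 to 9.51) and Kdm5d at 2.70 (others 6.83 to 7.15). Rbpj read 6.78 in wildtype replicate 5 (others 7.28 to 7.45). Zfp280d read 9.42 in null replicate 7 (others 9.11 to 9.19). The dimmer Fbln1 probe set read 2.88 in null replicate 7 (others 2.26 to 2.40), still below every wildtype array. The neuronal list score of null replicate 8 was -0.336 (others 0.108 to 0.285), although the list as a whole was higher in null tissue.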

How the results depend on the processing

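The actin covariate and the fit without wildtype replicates 1 and 2 together were chosen after seeing the data. The count of 2 called probe sets was 1 without a filter or with the ordinary linear model, 8 with an intensity trend and robust variances, 34 with a log2 6 filter or with array weights, 0 with the sex covariate, the actin covariate or without wildtype replicates 1 and 2 together, 46 at an adjusted p of 0.1, and 0 to 7 with 1 array left out. It stayed at 2 under median centring, quantile normalization, the floor and the 1.5-fold threshold. The stricter filter tests fewer probe sets, and the cause of the other shifts was not tested. The Fbln1 log2 fold change on the brighter probe set ran from -2.06 to -1.74 with 1 array left out, and that on the dimmer one from -1.27 to -0.94. The FGF list median of 0.28 ran from 0.19 to 0.45 with 1 array left out. By its unadjusted p it did not pass with the actin covariate (0.15, p = 0.0997), without null replicate 7 (0.19, p = 0.0606), with an estimated correlation (0.28, p = 0.117), or fry, directional (0.28, p = 0.137) or mixed (0.28, p = 0.234). By its adjusted p over the lists it also did not pass without a filter, with the log2 6 filter, array weights, the sex covariate or the mean of a gene's probe sets, or without wildtype replicate 3, 4 or 5 or null replicate 3 or 4 (adjusted p = 0.0514 to 0.131). The count of 4 lists was 1 without a filter (cell cycle, 0 of the 4), 2 with the actin covariate (Hedgehog, 1 of the 4, and neural progenitors), 2 with fry's mixed test (the stress lists, 0 of the 4), 0 with the log2 6 filter, the sex covariate, an estimated correlation, the mean of a gene's probe sets or fry's directional test, and 0 to 4 with 1 array left out. Of 438 alternatives for named genes, 385 stayed on their side of the threshold, 23 lost and 30 gained the call, and 0 reversed. All 23 losses were of the 2 called genes. Pole4 lost its call in 10 settings and kept it in 12, and Htatsf1 lost it in 13 and kept it in 9. Without wildtype replicates 1 and 2 together 5 lists passed, 3 of the 4 (not Hedgehog) and the matrix and neural crest lists. The list tests were not run with the ordinary linear model, since camera has no unmoderated form. Signals near the GCRMA floor limit Fbln1, Fgf8 and most FGF genes.

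Replicate numbers 3, 4 and 5 occur in both genotypes. Same-numbered arrays deviated together with r = -0.19, -0.34 and 0.16, so the numbers were not used as pairs, although 3 correlations cannot exclude shared litters. A replicate block on the numbers rests on the 3 shared ones and left 2 residual degrees of freedom. With the block the count of called probe sets was 0, and Fbln1 had -1.65 and -0.87 on its probe sets. The FGF list median was 0.50 (camera with the preset correlation, p = 0.000202). In that fit 6 lists passed, among them the matrix and neural crest lists, and the Hedgehog median turned to 0.0711. Of the 50 genes nearest Fbln1, 9 had an unadjusted p under 0.05 with the block (Fisher's exact p = 0.403).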

Other observations

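The tests of splits, neighbouring genes, the dimmer Pole4 probe set and the neuronal score were chosen only after the results were seen, while those of embryo sex, RNA integrity, array scaling, wildtype replicates 1 and 2 and gene families were written before their results, although the actin covariate and the fit without those replicates were added after the data were seen. Genes beside Fbln1 on its chromosome were among the larger differences. Celsr1, a cadherin of planar cell polarity and the 4th nearest gene tested, had a log2 fold change of -1.34 (SE 0.31, limma adjusted p = 0.116). Ift27, a small GTPase of intraflagellar transport and just outside the nearest 50, had -1.16, -1.23 and -0.65 on its 3 probe sets, of which the last 2 are of types that can match several genes. Apobec3, a cytidine deaminase that restricts retroviruses, had 0.58 (SE 0.15, limma adjusted p = 0.167). Of 14 families defined by gene symbol 0 passed camera, and the smallest adjusted p with an estimated correlation, for the spliceosome, was 0.588 (30 of 44 genes lower, or 68.2%, against 56.9% of all genes).

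The fall of Pole4 and Htatsf1 was set against embryo sex, RNA integrity and chance. Only wildtype replicate 4, and no null array, had a high Xist signal, so the sex fit cannot tell sex apart from that array. With the sex covariate the log2 fold changes were -0.93 (SE 0.12) and -0.94 (SE 0.14), and with the actin covariate -0.90 (SE 0.13) and -0.96 (SE 0.16). The largest changes in size, where a negative sign means a smaller size, were -0.457 standard errors with sex and -0.708 with actin. The adjusted p values were 0.0555 and 0.0598 with sex and 0.0790 and 0.109 with actin, so the calls ended while the sizes stayed within 1 standard error. Of 100 splits of the arrays run out of 126 possible, the real one counted here and below, 3 gave as many probe sets. This is a share under 0.05 of the splits run, and those not run could change it. Among the 3, 1 that exchanged wildtype replicate 3 with null replicate 8 gave 10. That split keeps most arrays with their genotype and leaves a further structure of the samples untested. The dimmer Pole4 probe set, with a log2 fold change of 0.0742, leaves a signal specific to 1 probe set as a candidate explanation for that gene, and a change of the Pole4 transcript in null tissue stays open.

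The excess of lower probe sets, 69.1% of those at an unadjusted p of 0.05, may come from array scaling, since the share was 53.3% after quantile normalization, though it was 65.8% after median centring. Leaving out wildtype replicates 1 and 2 together gave 64.2%, leaving out wildtype replicate 2 alone 62.2% and null replicate 5 alone 62.6%. Wildtype replicates 1 and 2 thus do not account for all of the excess, but a part is not excluded. Of 100 splits, 7 gave as many as the 1215 probe sets, with a highest of 1790, so chance cannot be excluded for the number, and 2 gave both as many and as one-sided a share. A second count, on the share alone, was added after that result had been seen, and there 26 splits were as one-sided, with a highest of 84.4%, so chance cannot be excluded for the share itself. An effect of genotype on many transcripts stays open.

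A hypothesis is that genes beside Fbln1 differ because the gene-trap chromosome may carry sequence variants of another strain. Of the 50 nearest genes tested, 14 (28%) had an unadjusted limma p under 0.05, 8 lower and 6 higher, against 12.7% elsewhere (odds ratio 2.67, 95% interval 1.32 to 5.10, Fisher's exact p = 0.00423, adjusted p = 0.0211 over 5 windows). Of 100 splits 1, the real one, gave as small a p, and the next smallest was 0.0278 against 0.00323, one-sided. The lower Pim3 and Ift27 raised the hypothesis, and Pim3 is among the 14 genes. Both tests thus partly reuse the values that raised it, which favours the real grouping. The result depended on the window, with Fisher's exact p = 0.124 for 25 genes, 0.131 for 100 and 0.453 for 200, and for 50 genes it was 0.140 with the actin covariate, 0.0735 without wildtype replicates 1 and 2 and 0.0575 with a log2 6 filter. An effect of fibulin-1 loss on Celsr1 or Pim3 stays open, and neighbouring genes are not independent.

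The list results were within reach of chance groupings of the arrays. Of 100 splits 19 gave as small a camera p for the FGF list, the smallest being 4.06e-05 against 0.00584, and 27 gave as many lists past the threshold, with up to 7 against 4. The per-array difference between the neuronal and progenitor list scores was 0.19 ± 0.11 (SD, n = 5) in null and -0.19 ± 0.28 in wildtype tissue (exact permutation p = 0.0238, and 0.00794 to 0.0476 with 1 array left out). Alone, the neuronal score had an exact permutation p of 0.405 and the progenitor score 0.127. More advanced null embryos may be the reason for the difference, as a hypothesis, but the progenitor list alone had a camera p of 0.0513. The difference also uses the neuronal list that raised the question, so the test does not decide.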
